A study of Vitis with 64 samples.

How the data were processed

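RNA was sequenced from berry skin and pulp of Frontenac and Marquette grapes at 18, 20, 22 and 24 °Brix, 4 libraries in each of 16 groups. Per the labels, each replicate came from its own block of a randomized block trial, the berries of a replicate were separated into skin and pulp, and 2 replicates of each group were sequenced single end and 2 paired end with strand-specific kits, without saying which. The replicates are therefore separate plots of vines, and skin and pulp with the same cultivar, Brix level and number come from the same berries. The submitters' processing notes name FastQC, cutadapt, Trimmomatic, HISAT2, StringTie and DESeq2, with no versions, roles or order. The genome build, the annotation, the strand setting and the program that made each table are not given in the sources used here.

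The deposited count table holds whole-number counts per gene identifier with no normalization seen, for 42414 identifiers, 14366 of them at 0 in every library. The deposited FPKM table holds FPKM made by the authors for 42411 identifiers, and the sequencing depth behind it is not given in the sources used here, so no interval or floor is given for an FPKM value. The 3 identifiers absent from the FPKM table have 14 counts over all libraries. Total counts per library ranged from 130209 to 2502043. Intervals of shares are Wilson 95% intervals, ratios of small counts carry exact conditional binomial intervals, and a group at 0 was given a floor of 3 counts over the group. All of these cover counting error only, since reads without molecular identifiers are not independent molecules. In the FPKM table a value of 0 is described as listed at 0.

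The count analysis was fixed before the data were examined. Genes were kept with filterByExpr (minimum count 10) on the 16 groups, which left 5314, and were scaled by TMM and fitted in edgeR 4.0.16 under R 4.3.3 with quasi-likelihood (glmQLFit and glmQLFTest), all 64 libraries in the same model with 47 residual degrees of freedom. The 13 comparisons were 24 against 18 °Brix in each cultivar and tissue, skin against pulp in each cultivar and Marquette against Frontenac in each tissue (both averaged over the Brix levels), and the differences of these changes between cultivars and between tissues. Signs are 24 minus 18 °Brix, skin minus pulp and Marquette minus Frontenac. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, within each comparison, with higher and lower genes counted apart. A batch term followed a rule fixed beforehand, because the labels do not say which libraries were paired end. Of the first 3 principal components of residual log2 CPM (prior count 2), the rule takes that whose sign parts most groups 2 against 2, if it parts at least 14. Component 3 parted all 16 groups and entered the model, although it held 3.10% of the residual variance. Component 1 held 45.9% and parted 14 groups, and its sign put 62 of the 64 libraries on the side of their set in the FPKM (gene-rich or gene-poor). The order of the samples in the series parts these sets too, with the 32 gene-poor libraries before the 32 gene-rich ones. The rule did not use that order. The batch of the rule is the gene-poor set in the Frontenac libraries against the gene-rich set in the Marquette libraries, so the values within each set stand beside each count result. For comparisons within a cultivar these come from each batch alone. The fit of one set in a cultivar then also held the other set of the other cultivar. For comparisons between the cultivars each set was fitted alone.

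The analysis of the FPKM was chosen after seeing the data. Libraries with more than 15000 identifiers above 0 FPKM were called gene-rich, 32 in all and 2 per group. Genes at 1 FPKM or more in at least 2 of them were kept (19446), and log2(FPKM + 1) was fitted with limma 3.58.1 (lmFit and eBayes with trend) over the 16 groups with 16 residual degrees of freedom, with the same comparisons and the same threshold. No batch term was used. Log2 changes of the FPKM are on the scale with 1 added. Principal components and the shares of variance were computed from the same values with each gene centred.

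Named identifiers followed a rule fixed before the data were examined. Because neither table pairs identifiers with names, the rule allows at most 2 identifiers that rose and 2 that fell per comparison. Taken were the identifiers with the largest rise and the largest fall among those past the threshold with a mean of at least 2 on the log2 CPM scale, and, chosen after seeing the data, the same from the FPKM with a mean of at least 2 on its log2 scale. The values of a named identifier in another comparison are given where the change is compared between cultivars or tissues. The 25 gene lists that had been fixed beforehand, with their tests by camera and fry, could not be matched to any identifier and were not tested.

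Before replicates were averaged, pairs of libraries of each group were compared. No 2 libraries held identical FPKM, and over the 96 pairs the lowest chi-square per degree of freedom of their counts was 1.71, above the sampling noise of 1. Whether replicate numbers pair libraries was checked by correlating the deviations from the group means. For skin and pulp of the same berries, r was −0.043 to 0.509 in 7 comparisons (median 0.264), above 0.1 in 5. Between Brix levels, which share a number and at most a block, r was −0.371 to 0.461 in 21 comparisons (median 0.099), above 0.1 in 10. Skin and pulp of the same berries were therefore also fitted with the berry sample as a block, and all comparisons with the replicate number as a block.

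The alternatives were RLE size factors and the Wald test of DESeq2 1.42.0, no filter on low counts, no batch term, replicate blocks, only the groups of a comparison, a linear slope over Brix, limma on the FPKM of all libraries with a pseudocount of 1 or 0.1, each batch alone, and each library left out in turn. Those chosen after seeing the data were the library set as the batch term, the gene-rich or the gene-poor set alone, the FPKM analysis with a pseudocount of 0.1, without its filter, rescaled by the upper quartile (factors 0.857 to 1.09), and all results without the 2 libraries of highest total count. Other splits of the libraries into groups were counted for every result with at least 3 libraries per group, with the real one included. These were all 35 splits of the 8 libraries for ripening in the counts, 35 drawn with a fixed seed for the tissue and cultivar results in the counts and for the differences of ripening, and 100 drawn in the FPKM, each with labels exchanged within a Brix level for tissue and cultivar. After seeing the data, the splits for ripening that keep 2 gene-rich and 2 gene-poor libraries on each side were also counted by themselves, splits that keep the skin and pulp of a berry sample together were counted for tissue with the sample as a block (35 drawn in the counts, 100 in the FPKM, and all 35 in the counts for the differences of ripening between tissues), and the bounds on named identifiers were also taken without the 2 libraries of highest total count.

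The models were tested on simulated data with changes put into 200 genes of libraries drawn from the mean levels, library sizes and spreads of the real ones. In the counts, of the genes changed 2-, 4- and 8-fold, edgeR recovered 1.49%, 25.4% and 40.9% for ripening in Frontenac pulp and 26.9%, 74.6% and 98.5% for skin against pulp in Frontenac, and called 1 and 6 unchanged genes. In the FPKM limma recovered 79.1%, 98.5% and 97.0% for ripening, and called 14 unchanged genes. Each gene was drawn independently, without the split into gene-rich and gene-poor libraries or other structure shared by genes. The numbers of unchanged genes called therefore do not measure false calls in the real data.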

Results

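The skin and the pulp of ripening berries were profiled by RNA sequencing in Frontenac and Marquette, wine grape cultivars bred as cold-hardy hybrids of several grape species. Berries were taken at 18, 20, 22 and 24 °Brix, a measure of dissolved solids that rises as sugar accumulates. The 16 groups of 2 cultivars, 2 tissues and 4 Brix levels held 4 libraries each, 64 libraries in all. Per the labels each replicate came from its own block of vines in the field. Total counts per library ranged from 130209 to 2502043, with a median of 379436, over 42414 gene identifiers. Neither deposited table pairs the identifiers with gene names, so genes appear here by identifier alone and few are named.

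The libraries fell into 2 sets in the deposited FPKM (fragments scaled by gene length and library size). In 32 libraries, 2 in every group and called gene-rich here, between 20988 and 24858 identifiers were above 0 FPKM. In the other 32, called gene-poor, between 3678 and 7040 were. A single identifier, Vitvi05g00715, took a median of 47.8% of a library's counts, from 6.11% (Wilson 95% interval 6.08 to 6.14%) in Marquette pulp at 18 °Brix replicate 3 to 79.5% (79.4 to 79.5%) in Marquette pulp at 22 °Brix replicate 4. Its FPKM lay between 146676 and 459602 in the gene-poor libraries and between 0.706 and 1022 in the gene-rich ones. Across genes, which are not independent replicates, Pearson r between log2 count and log2 FPKM of the same library was 0.817 to 0.857 in the gene-poor libraries. It was 0.25 to 0.577 in 30 gene-rich libraries, and 0.905 and 0.885 in Marquette pulp at 18 °Brix replicate 3 and Marquette skin at 22 °Brix replicate 3, the libraries with the highest totals (2502043 and 2163086). Each comparison is therefore given from both tables. The FPKM values come from the gene-rich libraries, 2 per group, tested with limma over 19446 genes, and were chosen after the data had been seen. The count values come from all 64 libraries, 4 per group, tested with edgeR over 5314 genes, as fixed beforehand. Within a cultivar, count values for one library set compare only that set. Their fit also held the other set of the other cultivar, which shares in the estimate of spread. For every identifier named from the FPKM, each library on one side of its comparison lay above each library on the other side. These identifiers were chosen for the largest changes in the same libraries, so this separation adds no support.

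**Figure D1:**
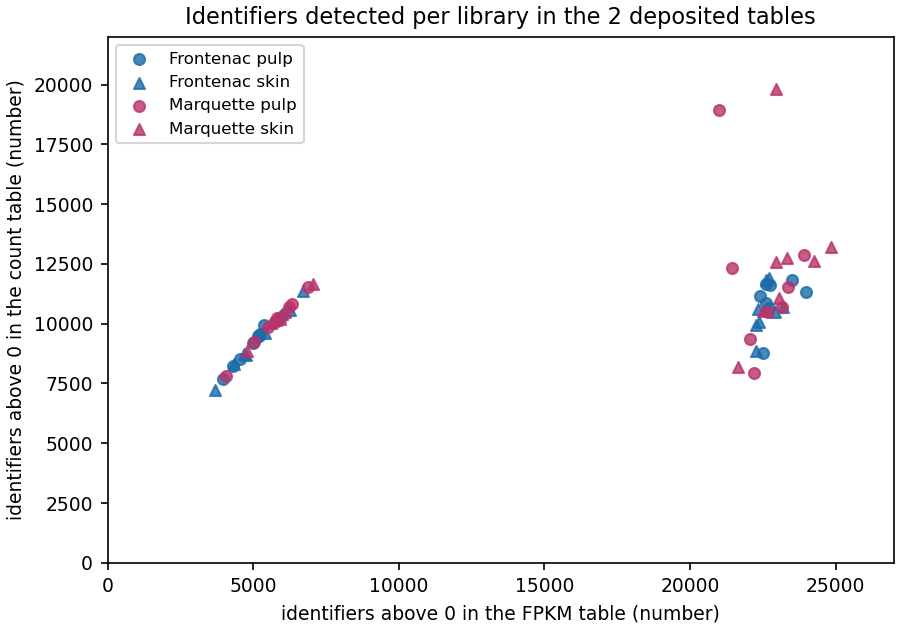
Each of the 64 points is a library, placed by its number of identifiers above 0 in the FPKM table (horizontal) and in the count table (vertical), with colour for cultivar and shape for tissue. The 32 gene-poor libraries hold at most 7040 identifiers above 0 FPKM and the 32 gene-rich ones at least 20988, while in the count table only Marquette pulp at 18 °Brix replicate 3 (18925) and Marquette skin at 22 °Brix replicate 3 (19821) hold more than 13206.

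In the gene-rich libraries tissue separated the samples first. The first principal component of log2 FPKM held 49.1% of the variance, and 98.4% of its spread lay between skin and pulp. Cultivar and Brix level shared the second (16% of the variance) and the third component (12.5%). Over all genes, tissue held 48.3% of the variance, Brix level 17.0% and cultivar 14%, while the 16 groups together held 94.2%. The 2 libraries of a group correlated at r of 0.972 to 0.998 across genes.

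**Figure D2:**
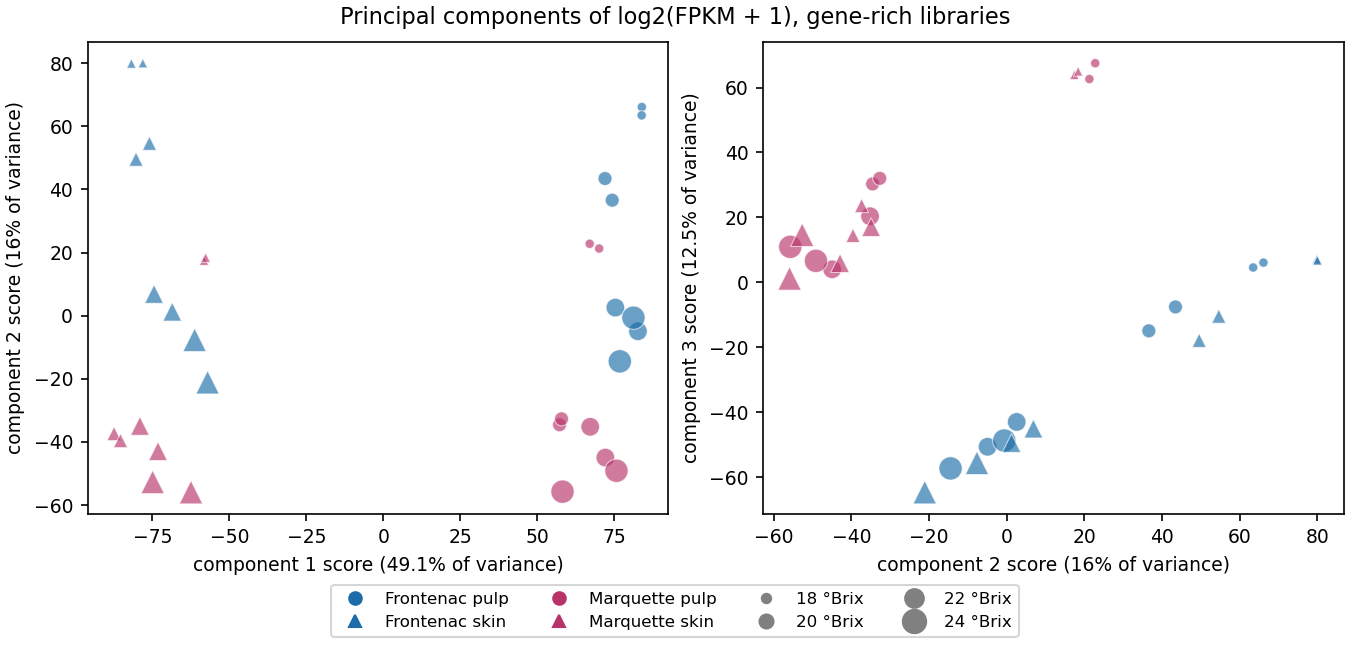
Scores of the 32 gene-rich libraries on the first 3 principal components of log2(FPKM + 1), with colour for cultivar, shape for tissue and point size for Brix level. Skin and pulp lie apart on component 1, which holds 49.1% of the variance, and cultivar and Brix level spread the libraries on components 2 (16%) and 3 (12.5%).

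The question put to the ripening series was which transcripts change in pulp between 18 and 24 °Brix. Vitvi19g00435 fell steeply in the pulp of both cultivars. Its level in Frontenac went from 3059 ± 143 FPKM (SD, n = 2) at 18 °Brix to 7.99 ± 2.21 at 24 °Brix, a log2 change of −8.43 (SE 0.53, limma adjusted p = 5.16e-10). In Marquette it went from 526 ± 62.8 to 14.4 ± 5.30 FPKM, a log2 change of −5.14 (SE 0.53, limma adjusted p = 2.77e-07), and the fall was steeper in Frontenac (difference of log2 changes 3.30, SE 0.75, limma adjusted p = 0.00444). The counts of Vitvi19g00435 gave a log2 change of −7.70 in Frontenac pulp (SE 0.90, edgeR adjusted p = 1.11e-06, n = 4 per level). Vitvi07g02269 fell in Marquette pulp from 1225 ± 136 to 16.1 ± 1.75 FPKM (log2 −6.16, limma adjusted p = 8.15e-08, and −8.26 in the counts, edgeR adjusted p = 2.69e-07) and in Frontenac pulp from 3406 ± 272 to 78.4 ± 23.8 FPKM (log2 −5.45, limma adjusted p = 2.91e-07). Its 2 falls did not differ past the threshold (difference −0.71, SE 0.81, limma adjusted p = 0.59).

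Among identifiers that rose in pulp, Vitvi17g01613 went from 3.70 ± 1.27 to 365 ± 163 FPKM (SD, n = 2) in Marquette (log2 6.23, SE 0.70, limma adjusted p = 6.88e-07). The counts of Vitvi17g01613 did not show this rise, with 5 at 18 °Brix and 3 at 24 °Brix summed over 4 libraries each. At each of these levels 3 of the 4 libraries were at 0 counts. Scaled by library size the ratio of 24 to 18 °Brix was 1.40 (counting interval 0.218 to 7.21), so the direction in the counts stays open. Vitvi17g01613 stood at 5.41 ± 0.492 and 4.48 ± 2.98 FPKM in Frontenac (limma adjusted p = 0.739). The cultivars differed in its change in the FPKM (difference 6.57, SE 0.98, limma adjusted p = 0.000157). Vitvi11g00564 rose in Frontenac pulp from 7.07 ± 8.90 to 305.8 ± 0.295 FPKM (log2 5.92, SE 0.72, limma adjusted p = 1.71e-06), with 0 counts at 18 °Brix and 20 at 24 °Brix summed over 4 libraries. Vitvi11g00086 had 0 counts in Frontenac pulp at 18 °Brix and 46 at 24 °Brix, at least 12.5-fold higher with the floor of 3 counts taken over the group (edgeR adjusted p = 0.000168). In the gene-rich Frontenac libraries Vitvi11g00086 changed by log2 6.94 (edgeR adjusted p = 0.000163), and in the gene-poor ones by 6.76 without a call (edgeR adjusted p = 0.199). Its FPKM were 12.3 ± 2.45 and 9.66 ± 0.83, a log2 change of −0.31 (limma adjusted p = 0.338). Vitvi08g01458 had 0 and 59 counts in Marquette pulp, at least 46-fold higher (edgeR adjusted p = 0.000429), or at least 7.93-fold without the 2 libraries of highest total count, and its FPKM at 24 °Brix was 0.391 ± 0.0622.

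In the FPKM of Frontenac pulp, limma called 9081 genes between 18 and 24 °Brix (4134 higher and 4947 lower at 24 °Brix), of which 868 rose and 2398 fell at least 2-fold. Marquette pulp had 9306 (5242 higher, 4064 lower), with 1347 and 1858 at least 2-fold. In the counts, edgeR called 433 genes in Frontenac pulp (223 higher, 210 lower) and 881 in Marquette pulp (335 higher, 546 lower). Of the count-called genes that were tested in both tables, 65.0% in Frontenac pulp and 77.1% in Marquette pulp had the same sign of change in the FPKM. That overlap lay mainly in the falls. Genes lower in both tables numbered 119 in Frontenac pulp and 349 in Marquette pulp, against 45 and 140.6 from chance overlap, while genes higher in both numbered 50 and 71, against 52.2 and 58.2. The gene-rich libraries enter both analyses, so the calls are not independent. An excess over chance overlap is therefore not separate evidence of a change with ripening. Within the gene-rich and the gene-poor libraries of each cultivar, fitted beside the other set of the other cultivar, the count results were 582 and 27 in Frontenac pulp and 1061 and 631 in Marquette pulp. The Frontenac count result was 270 without the 24 °Brix replicate 3; the Marquette result was 426 without replicate 3 and 1325 without replicate 4 at 18 °Brix, 523 and 529 without replicates 3 and 4 at 24 °Brix, 1478 (305 higher, 1173 lower) when scaled by the RLE size factors of DESeq2, and 8 when its own groups were fitted alone. Fitting only the groups of a comparison gave 986 in the counts of Frontenac pulp, and 5379 and 5558 in the FPKM of Frontenac and Marquette pulp. Frontenac pulp had 149 in the counts without the filter on low counts, and Marquette pulp 1839 with the DESeq2 Wald test. Marquette pulp also had 1719 with the library set as the batch term, and 487 without the 2 libraries of highest total count.

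In skin the same question gave other identifiers as the largest changes, though some of them changed in pulp too. Vitvi15g00643 rose in Frontenac skin from 6.89 ± 0.798 FPKM (SD, n = 2) at 18 °Brix to 712 ± 122 at 24 °Brix (log2 6.49, SE 0.24, limma adjusted p = 5.13e-14). In the counts Vitvi15g00643 rose from 0 to 26, at least 7.08-fold (edgeR adjusted p = 0.0169). The rise was smaller in Marquette skin (difference of log2 changes −5.10, SE 0.34, limma adjusted p = 2.21e-09). Vitvi14g01750 rose in Marquette skin through every Brix level, from 0.0604 ± 0.0353 through 13.7 ± 3.49 and 54.5 ± 18.1 to 171 ± 87.1 FPKM (log2 7.24, SE 0.26, limma adjusted p = 2.83e-13). In Frontenac skin it was listed at 0 FPKM at 18, 20 and 24 °Brix, and the cultivars differed in the change (difference 7.24, limma adjusted p = 1.04e-10). Vitvi01g01922 fell in Marquette skin from 156 ± 4.71 to 0.297 ± 0.0128 FPKM (log2 −6.92, SE 0.75, limma adjusted p = 4.92e-07). Vitvi03g01899 was listed at 4814 and 7336 FPKM in the Frontenac skin libraries of 18 °Brix and at 0 in both of 24 °Brix (limma adjusted p = 2.48e-05), while its counts summed to 65 and 58 over 4 libraries each (edgeR adjusted p = 0.921).

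Some identifiers were called in skin by the counts with little or no change in the FPKM. Vitvi02g00795 had 0 counts at 18 °Brix and 210 at 24 °Brix in Frontenac skin, at least 57.2-fold higher (edgeR adjusted p = 6.04e-08), with 33.5 ± 3.20 and 28.7 ± 0.733 FPKM (SD, n = 2; limma adjusted p = 0.261). Vitvi11g00144 had 126 counts at 18 °Brix and 0 at 24 °Brix in Frontenac skin, at least 51.4-fold lower (edgeR adjusted p = 3.54e-05), and was listed at 0 FPKM in the libraries of both levels. Vitvi17g00284 fell in Marquette skin from 6166 counts to 24 (log2 −7.24, SE 0.99, edgeR adjusted p = 9.01e-07), with 0.0799 ± 0.025 and 0.128 ± 0.00136 FPKM. The fall of Vitvi17g00284 was log2 −8.05 in the gene-rich Marquette libraries (edgeR adjusted p = 0.000197) and −2.44 in the gene-poor ones (edgeR adjusted p = 0.0254). Vitvi14g02659 rose there in both tables, from 0 counts to 20, at least 7.79-fold (edgeR adjusted p = 0.0445), and from 12.6 ± 0.419 to 76.1 ± 10.4 FPKM (log2 2.5, limma adjusted p = 1.21e-08). The count call of Vitvi14g02659 was lost in 10 of 22 alternatives, among them the gene-rich Marquette libraries (edgeR adjusted p = 0.745).

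In the FPKM of Frontenac skin, limma called 9330 genes between 18 and 24 °Brix (4326 higher, 5004 lower), of which 1106 rose and 2547 fell at least 2-fold. Marquette skin had 8927 (5346 higher, 3581 lower, or 4353 and 4280 with upper-quartile scaling), with 1457 and 1511 at least 2-fold. In the counts, edgeR called 604 genes in Frontenac skin (340 higher, 264 lower) and 360 in Marquette skin (176 higher, 184 lower), and 68.2% and 74.5% of those tested in both tables had the same sign in the FPKM. Genes higher in both tables numbered 103 in Frontenac and 72 in Marquette skin, against 70.1 and 40.4 from chance overlap, and genes lower in both 133 and 83, against 58.7 and 31.5. As in pulp, the gene-rich libraries enter both analyses, so these excesses are not separate evidence. Within the gene-rich and the gene-poor libraries of each cultivar, fitted as for pulp, the count results were 843 and 120 in Frontenac skin and 36 and 452 in Marquette skin. They were 397 in Frontenac skin without the 24 °Brix replicate 3 and 239 in Marquette skin without the 24 °Brix replicate 1, and Marquette skin had 565 without the 2 libraries of highest total count. With only the groups of a comparison in the fit the counts gave 1431 in Frontenac and 1284 in Marquette skin, and the FPKM 5383 in Marquette skin. Without the filter on low counts there were 333 and 178, and the DESeq2 Wald test gave 572 in Marquette skin.

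**Figure D3:**
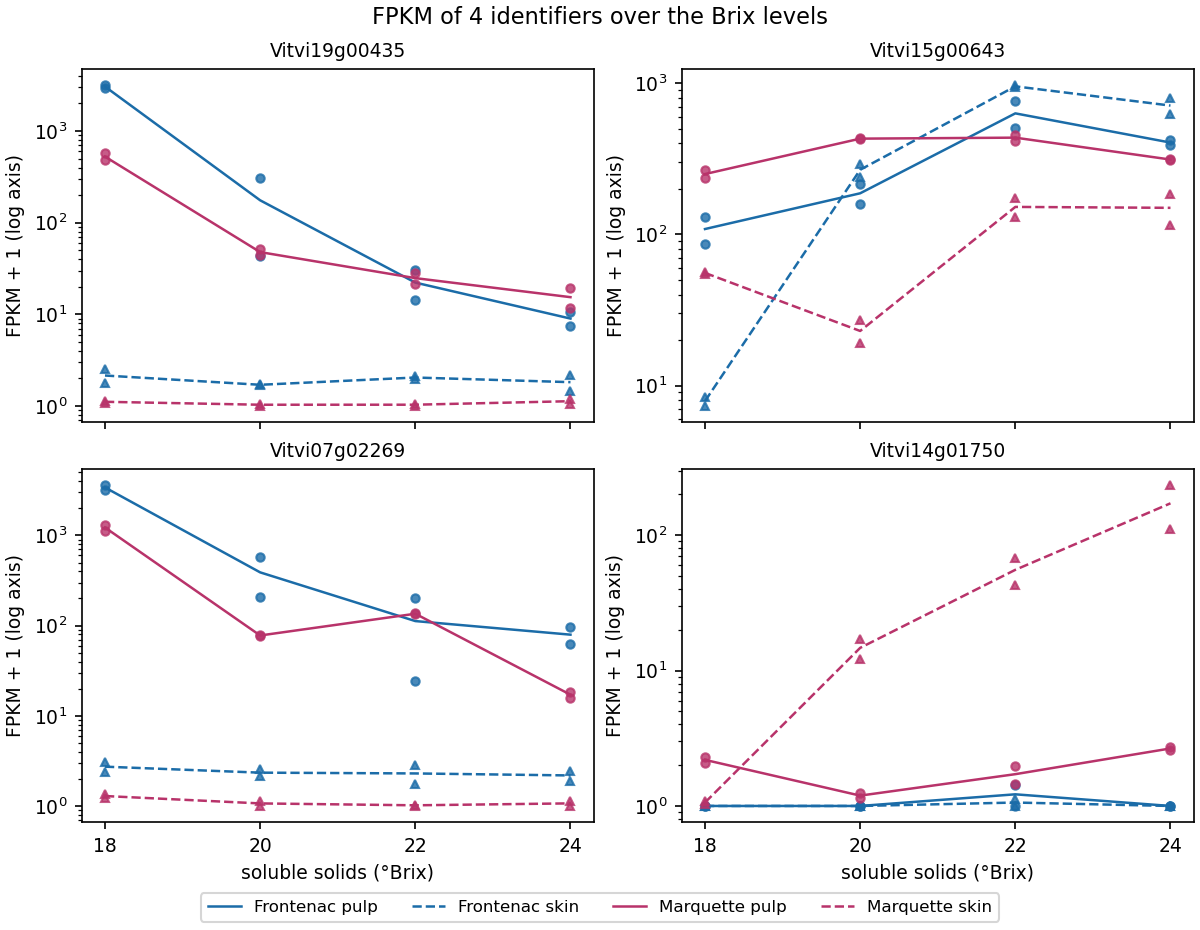
FPKM plus 1 (log axis) of 4 named identifiers against Brix level in the gene-rich libraries; points are libraries and lines join the means of 2 libraries per level, solid for pulp and dashed for skin. Vitvi19g00435 falls from 3059 to 7.99 FPKM in Frontenac pulp, and Vitvi14g01750 rises from 0.0604 to 171 FPKM in Marquette skin.

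Genes called in both cultivars, or in both tissues of a cultivar, mostly moved the same way with ripening. In pulp, 5563 genes were called by limma in the FPKM of both cultivars, and 94.3% of them moved the same way. They comprised 2639 genes that rose in both, against 1114 from chance overlap, and 2608 that fell in both, against 1034. In skin 5819 genes were called in both cultivars, 93.6% the same way. Between pulp and skin the shared calls moved the same way for 93.1% of 5640 genes in Frontenac and 93.5% of 5469 in Marquette. A core of 1465 genes rose and 1150 fell in both tissues of both cultivars, where independent calls would give 68.2 and 49.0. The core in the counts was 34 genes that rose and 27 that fell (0.0298 and 0.0371 from independent calls, edgeR). Skin and pulp come from the same berries, and all comparisons of a table share each gene's estimate of spread. The calls are therefore not independent, and an excess over these chance values does not measure a shared response. Many calls were not shared, since of the genes that rose or fell in at least 1 tissue of 1 cultivar, 3782 of 9208 and 3313 of 8530 in the FPKM did so in exactly 1, as did 397 of 666 and 599 of 850 in the counts. In the counts, the genes called in both were 222 between the cultivars in pulp, 186 in skin, and 204 and 152 between the tissues in Frontenac and Marquette.

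Genes whose change with ripening differed between the cultivars were found by a direct test of the difference. Vitvi17g01613 in pulp and Vitvi14g01750 in skin, described above, were among them. Both were named for the largest rise in Marquette in the same libraries, a choice that favours a difference from Frontenac. Testing the FPKM, limma called 3923 genes in pulp (2534 with the higher log2 change in Marquette, 1389 in Frontenac) and 3918 in skin (2760 and 1158). Testing the counts, edgeR called 34 in pulp (14 and 20) and 26 in skin (9 and 17), and within the gene-rich and gene-poor libraries alone 4 and 96 in pulp and 0 and 101 in skin, the 0 beside 196 genes at an unadjusted p under 0.05. With only its own groups in the fit the pulp result ended, at 0 genes in the counts (edgeR, 268 at an unadjusted p under 0.05), and fell to 1188 in the FPKM. The DESeq2 Wald test gave 207 in pulp and 74 in skin, and edgeR without the filter on low counts 7 and 10. The FPKM pulp result was 2584 without the 2 libraries of highest total count and 2560 without Marquette pulp at 24 °Brix replicate 3, and upper-quartile scaling split the skin result into 2034 and 1631. The count result of pulp was 7 without Frontenac pulp at 18 °Brix replicate 3, 22 and 20 without Frontenac pulp at 24 °Brix replicates 1 and 4, 15 and 72 without Marquette pulp at 18 °Brix replicates 3 and 4, and 18 without either replicate 3 or replicate 4 of Marquette pulp at 24 °Brix. With RLE size factors it was 77 (22 and 55), and that of skin 43 (20 and 23), while skin gave 15 without Frontenac skin replicate 1 or Marquette skin replicate 4, both at 18 °Brix.

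The change with ripening also differed between skin and pulp of a cultivar for a part of the genes. Vitvi19g00435, which fell in Frontenac pulp, stood at 1.15 ± 0.538 and 0.818 ± 0.509 FPKM (SD, n = 2) in Frontenac skin at 18 and 24 °Brix (skin minus pulp difference of log2 changes 8.19, SE 0.75, limma adjusted p = 1.25e-07). In Marquette the difference for Vitvi14g01750 was 6.96 (SE 0.37, limma adjusted p = 2.90e-10) and for Vitvi07g02269 5.89 (SE 0.81, limma adjusted p = 4.51e-05). Vitvi19g00435 in Frontenac skin and Vitvi07g02269 in Marquette skin (0.289 and 0.0685 FPKM) had little room to fall on the scale with 1 added. Each of these identifiers was named for its large change in 1 tissue of the cultivar, in the same libraries, which favours finding a difference. From the FPKM, limma called 4585 genes in Frontenac (2218 with the higher change in skin, 2367 in pulp) and 3919 in Marquette (2241 and 1678). With upper-quartile scaling both balances turned, to 2710 and 1989 in Frontenac and 1817 and 2402 in Marquette. From the counts, edgeR called 32 in Frontenac (26 and 6) and 62 in Marquette (30 and 32). These values do not pair the skin and pulp of the same berries. With the berry sample as a block the FPKM gave 5123 (2425 and 2698) and 4497 (2519 and 1978), and the counts 36 (27 and 9) and 109 (26 and 83). With only its own groups in the fit the counts gave 159 in Frontenac and 10 in Marquette, and the FPKM 1973 in Marquette. The DESeq2 Wald test gave 69 and 651. Within the gene-rich and the gene-poor libraries of each cultivar, fitted beside the other set of the other cultivar, the count results (edgeR) were 54 and 0 in Frontenac, the 0 beside 164 genes at an unadjusted p under 0.05, and 4 and 20 in Marquette. With RLE size factors the Marquette result was 315 (264 and 51). Leaving out 1 library took it to 117 (pulp at 18 °Brix replicate 1), 337 (pulp at 18 °Brix replicate 4), 39 (pulp at 24 °Brix replicate 3) and 37 (skin at 18 °Brix replicate 3), and the FPKM result of Marquette to 2505 and 2453 without the last 2 of these. The Frontenac count result was 21 without pulp at 24 °Brix replicate 4 and 14 without skin at 18 °Brix replicate 4.

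Skin and pulp were compared over all 4 Brix levels to find the transcripts that mark each tissue. The values below do not pair the skin and pulp of the same berries. Vitvi08g00854 was far higher in skin, at 15759 ± 2951 FPKM (SD, n = 8) in Frontenac skin against 64.8 ± 30.9 in pulp (log2 8.01, SE 0.22, limma adjusted p = 2.05e-17) and at 17460 ± 7920 against 32.8 ± 10.2 in Marquette (log2 8.97, SE 0.22, limma adjusted p = 4.11e-18). The counts gave log2 differences of 7.85 and 7.51 for Vitvi08g00854 (edgeR adjusted p = 7.54e-20 and 3.62e-21, n = 16 per tissue). In pulp, Vitvi14g01937 stood at 3547 ± 3237 FPKM in Frontenac against 5.37 ± 1.76 in skin (log2 −8.61, limma adjusted p = 7.87e-17) and was also lower in Marquette skin (log2 −8.95, limma adjusted p = 5.60e-17). An SD over 8 libraries takes in the spread between Brix levels. Vitvi14g01937 in Frontenac pulp had means of 8361, 2735, 2060 and 1030 FPKM at 18, 20, 22 and 24 °Brix. Vitvi07g02127 stood at 3628 ± 2643 FPKM in Marquette pulp against 4.18 ± 1.28 in skin (log2 −9.23, SE 0.14, limma adjusted p = 3.88e-21, and −9.72 in the counts, edgeR adjusted p = 3.45e-25). Vitvi10g00940 was higher in skin in the counts of both cultivars (log2 8.02 and 8.16, edgeR adjusted p = 1.43e-21 and 7.82e-20), at mean levels in skin of 0.885 and 0.331 FPKM. Vitvi05g02117 had 2069 counts in Frontenac pulp and 1 in skin, a ratio of 2282 (95% counting interval 409 to 90162, edgeR adjusted p = 5.05e-18), and was listed at 0 FPKM in the 16 gene-rich libraries of Frontenac.

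In the FPKM limma called 13113 genes between skin and pulp in Frontenac (7957 higher in skin, 5156 higher in pulp) and 12329 in Marquette (7002 and 5327). The larger number in skin depended on the scaling, since rescaled by the upper quartile these were 6804 and 6552 in Frontenac and 6356 and 6236 in Marquette. At least 2-fold differences made up 2445 and 1428 of them in Frontenac and 2152 and 1230 in Marquette. The cultivars shared 10123 of these genes, 97.0% with the same direction. With the counts, edgeR called 1588 genes in Frontenac (854 higher in skin, 734 in pulp) and 1434 in Marquette (785 and 649), and 80.02% and 83.7% of those tested in both tables had the same sign in the FPKM. Within the gene-rich and the gene-poor libraries of each cultivar, fitted beside the other set of the other cultivar, the count results were 1803 and 925 in Frontenac and 897 and 1387 in Marquette. With the berry sample as a block, the FPKM gave 11776 in Frontenac and 10006 in Marquette (limma), and the counts 1712 and 1466 (edgeR).

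The difference between skin and pulp was itself compared between the cultivars. Vitvi06g00182 was 4.88 higher in skin than in pulp on the log2 scale in Marquette and 0.62 higher in Frontenac (difference 4.25, SE 0.18, limma adjusted p = 5.18e-13). Vitvi08g01734 was lower in skin than in pulp by −7.08 in Frontenac and −0.83 in Marquette (difference 6.25, SE 0.21, limma adjusted p = 1.54e-14). Both identifiers were named for a large difference between the cultivars in 1 tissue, which favours such a result. Testing the FPKM, limma called 5345 such genes (2155 with the higher log2 ratio of skin to pulp in Marquette, 3190 in Frontenac, or 2537 and 2663 with upper-quartile scaling), and 1897 (836 and 1061) when the skin and pulp of the same berries were kept together as a block. On the counts, edgeR called 114 (65 and 49), and 8 and 117 within the gene-rich and the gene-poor libraries alone.

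Frontenac and Marquette were compared within each tissue over all Brix levels. Vitvi08g01734 stood at 237 ± 197 FPKM (SD, n = 8) in Frontenac pulp and was listed at 0 in 6 of the 8 libraries of Marquette pulp (log2 −6.66, SE 0.15, limma adjusted p = 2.47e-18, and −2.73 in the counts, edgeR adjusted p = 0.000136). Its means in Frontenac pulp were 546, 112, 159 and 132 FPKM from 18 to 24 °Brix, and SDs over 8 libraries take in such spread between levels. Vitvi19g01883 stood at 120 ± 55.5 FPKM (SD, n = 8) in Marquette pulp against 1.28 ± 1.24 in Frontenac pulp (log2 5.67, SE 0.40, limma adjusted p = 2.84e-10), with 29 and 17 counts over 16 libraries each. Scaled by library size these counts gave a ratio of 1.01 (95% counting interval 0.54 to 1.96), so they did not show this difference. In skin, Vitvi06g00182 stood at 102 ± 30.9 FPKM in Marquette against 1.16 ± 0.605 in Frontenac (log2 5.56, limma adjusted p = 2.5e-18, and 5.35 in the counts, edgeR adjusted p = 7.89e-10). Vitvi01g01981 was higher in Frontenac skin, at 429 ± 306 against 7.99 ± 12.0 FPKM (log2 −6.13, limma adjusted p = 3.15e-17, and −4.29 in the counts, edgeR adjusted p = 5.40e-07). Vitvi03g00603 had 0 counts in all Marquette libraries and 670 in Frontenac pulp and 1844 in Frontenac skin, at least 377-fold and 1029-fold higher, or 231-fold and 696-fold without the 2 libraries of highest total count (edgeR adjusted p = 1.25e-17 and 5.00e-20), and the limma differences in FPKM were −1.14 and −2.10 (adjusted p = 2.33e-13 and 8.43e-18). Vitvi01g01910 had 1809 counts in Marquette pulp and 1 in Frontenac pulp, a ratio of 1071 (95% counting interval 192 to 42311, or 1696 without the 2 libraries of highest total count, edgeR adjusted p = 1.07e-16), and 3120 and 0 in skin (edgeR adjusted p = 1.94e-17), at mean levels of 0.179 and 0.196 FPKM in Marquette pulp and skin.

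From the FPKM, limma called 10634 genes between the cultivars in pulp (6180 higher in Marquette, 4454 in Frontenac, or 5502 and 5249 with upper-quartile scaling) and 10464 in skin (5463 and 5001). At least 2-fold differences made up 822 and 665 of them in pulp and 815 and 775 in skin. The tissues shared 7111 of these genes, 93.2% with the same direction. In the counts edgeR called 1357 genes in pulp (784 higher in Marquette, 573 in Frontenac) and 1213 in skin (701 and 512). The pulp balance moved with the analysis, to 1131 and 571 with RLE size factors, 1348 and 630 with the DESeq2 Wald test, 665 and 650 without the 2 libraries of highest total count and 916 and 934 without the filter on low counts. In skin RLE gave 887 and 507. Of the genes called in pulp and skin by edgeR, 76.5% and 74.4% of those tested in both tables had the same sign in the FPKM. Within the gene-rich and the gene-poor libraries alone the count results were 922 and 1346 in pulp and 803 and 1334 in skin. The median log2 difference over all genes in the counts was 0.271 in pulp and 0.274 in skin, and the count table's median change with ripening in Marquette pulp was −0.367, so directions in these comparisons are relative to those shifts.

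**Figure D4:**
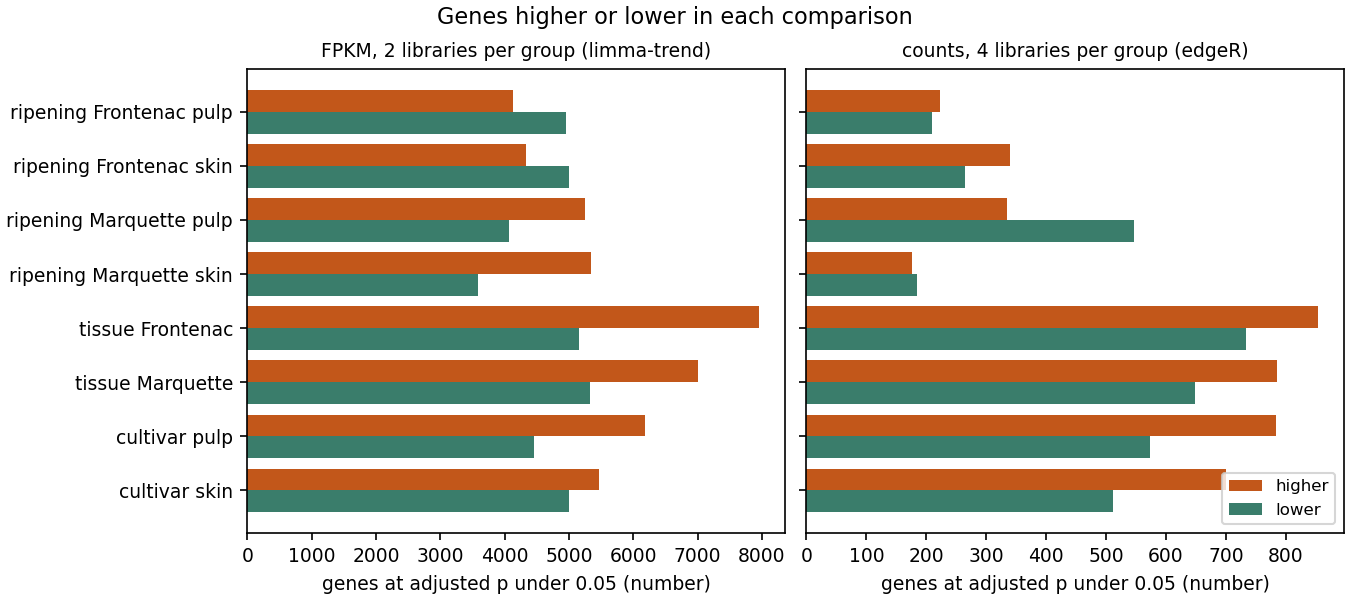
Bars give the number of genes higher (orange) and lower (green) at an adjusted p under 0.05, at 24 against 18 °Brix, in skin against pulp and in Marquette against Frontenac, for limma on the FPKM of the gene-rich libraries (left) and edgeR on the counts (right). Of the 8 comparisons the tissue comparison of Frontenac has the most genes in both tables, 13113 of 19446 and 1588 of 5314. In the counts this rank depends on the fit, since with RLE size factors cultivar in pulp had 1702 and tissue in Frontenac 1611.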

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

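The tests of the opposite strand, of low depth, of exchanged columns and of weaker strand marking were chosen only after the result they address had been seen.

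In 30 of the 32 gene-rich libraries the count table and the FPKM table ranked genes differently, with r across genes of 0.25 to 0.577. Low depth of the same molecules is argued against, since a median of 13.6% of the identifiers at 100 FPKM or more had 0 counts in the same library (range 3.96 to 36.8%). An exchange of columns is also argued against, since only 2 of the 64 count columns correlated above 0.7 with any gene-rich FPKM column. What stays open is that the counts of these libraries may have been taken on the strand opposite to that of the FPKM, because identifiers with at least 100 counts and under 1 FPKM had a neighbour in number at 100 FPKM or more 2.85 times as often as identifiers 10 numbers away (medians 14% and 5.09%, higher in 30 of 30 libraries). Vitvi05g00715 took a like share of the counts in both sets, with medians of 50.5% in the gene-poor and 47.7% in the gene-rich libraries. The match of counts and FPKM in the gene-poor libraries therefore does not show that their counts are free of the same problem, which was not tested. No biological explanation was tested.

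Marquette pulp at 18 °Brix replicate 3 and Marquette skin at 22 °Brix replicate 3 held 18925 and 19821 identifiers above 0 counts, against at most 13206 in the other 62 libraries. Greater depth is argued against as the whole cause, since thinned to the median total they still held 15282 and 16150. A wrong label is argued against, since the FPKM of both (2 of 2) correlated best with the other gene-rich library of their own group (r of 0.979 and 0.985). Weaker strand marking in these libraries may account for it, since in 2 of 2 the FPKM of Vitvi05g00715 (1022 and 438) was above the highest of the other 30 gene-rich libraries, 25.1. No biological explanation was tested.

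A library stood far from the other 3 of its group in 12 of 104 sets of 4 values tested, where chance gives 1 in 20. For 6 of the 12 the other 3 libraries were at 0 CPM, where a single count sets the result, so that rate does not apply to them. For total counts these were Frontenac skin at 22 °Brix replicate 3 (457817, others 293701 to 319931), Marquette pulp at 18 °Brix replicate 3 (2502043, others 275719 to 341943) and Marquette skin at 22 °Brix replicate 3 (2163086, others 207706 to 415398). For identifiers above 0 counts it was Marquette skin at 20 °Brix replicate 4 (12732, others 10221 to 10525). The share of counts on Vitvi05g00715 was 69.8% in Frontenac pulp at 24 °Brix replicate 2 (others 64.6 to 65.3%) and 6.11% in Marquette pulp at 18 °Brix replicate 3 (others 46.9 to 54.4%). In CPM, with the other 3 libraries at 0, Vitvi10g00940 stood at 4.88 in Frontenac pulp at 18 °Brix replicate 4, at 2.67 in Marquette pulp at 20 °Brix replicate 4 and at 2.22 in Marquette pulp at 24 °Brix replicate 1. Likewise Vitvi05g02117 stood at 2.31 CPM in Frontenac skin at 18 °Brix replicate 2, Vitvi07g02127 at 2.5 in Marquette skin at 20 °Brix replicate 3 and Vitvi01g01910 at 3.13 in Frontenac pulp at 18 °Brix replicate 1.

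Changes that differed between groups by a test of the difference itself were counted over all genes. In the FPKM (limma) the change with ripening differed between the cultivars for 3923 genes in pulp and 3918 in skin, and between the tissues for 4585 in Frontenac and 3919 in Marquette, and the skin to pulp difference differed between the cultivars for 5345. In the counts (edgeR) these were 34, 26, 32, 62 and 114 genes.

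Among named identifiers, the change with ripening in pulp, Marquette minus Frontenac, differed by 3.30 for Vitvi19g00435 and by 6.57 for Vitvi17g01613 in the FPKM, and by −7.65 for Vitvi11g00086 in the counts. In skin the same difference in the FPKM was −5.10 for Vitvi15g00643, 7.24 for Vitvi14g01750, −3.80 for Vitvi01g01922 and 14.83 for Vitvi03g01899, whose fitted value rests on libraries listed at 0. Skin minus pulp in Frontenac, the FPKM gave −3.07 for Vitvi11g00564, 8.19 for Vitvi19g00435, 4.56 for Vitvi15g00643 and −11.74 for Vitvi03g01899, and the counts −6.11 for Vitvi11g00086 and 6.57 for Vitvi02g00795. Vitvi11g00564 also rose in Frontenac skin, from a mean of 0.431 to 9.30 FPKM, against 7.07 to 305.8 in pulp. Skin minus pulp in Marquette, the FPKM gave −4.43 for Vitvi17g01613, 5.89 for Vitvi07g02269, 6.96 for Vitvi14g01750 and −3.55 for Vitvi01g01922, and the counts −5.70 for Vitvi17g00284. The skin to pulp difference, Marquette minus Frontenac, differed by 0.96 for Vitvi08g00854, −2.15 for Vitvi07g02127, 6.25 for Vitvi08g01734 and 4.25 for Vitvi06g00182 in the FPKM and by −2.53 for Vitvi07g02127 in the counts. All are differences of log2 changes, with adjusted p (limma or edgeR) between 1.54e-14 and 0.0415. With 1 added to the FPKM, changes at low FPKM are shrunk, so part of a difference can come from a side at low FPKM. The identifiers were named for large changes in these same libraries, so their choice favours such differences.

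The FPKM of the gene-poor libraries entered no comparison here except the limma alternative over all libraries. There, the median FPKM of Vitvi05g00715 was 286525, against 4.56 in the gene-rich libraries.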

How the results depend on the processing

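The library set as a batch term, the gene-rich and gene-poor sets alone, all alternatives to the FPKM analysis and those without the 2 libraries of highest total count were chosen after seeing the data. Results are named by tissue for ripening, by tissue or cultivar for those comparisons, and as differences for the tests of a difference. No change of a named identifier reversed under the alternatives run, which did not include the gene-rich FPKM for changes named from the counts. There Vitvi11g00086 and Vitvi02g00795 had the opposite sign without a call, at log2 −0.31 and −0.21 (limma adjusted p = 0.338 and 0.261). The others tested there kept their sign. The balance of higher and lower genes is less firm. In the counts it kept its side in every alternative only for tissue in Marquette and cultivar in skin. It turned in Frontenac pulp from 223 and 210 to 228 and 261 (RLE) and 262 and 320 (batch b alone), in Frontenac skin from 340 and 264 to 394 and 449 (batch b alone), in Marquette pulp from 335 and 546 to 344 and 321 (no filter), in Marquette skin from 176 and 184 to 232 and 195 (RLE), for tissue in Frontenac from 854 and 734 to 1190 and 1245 (no filter) and for cultivar in pulp from 784 and 573 to 916 and 934 (no filter). The tests of a difference in the counts turned too or, for ripening between tissues in Frontenac, came to 0 genes (edgeR, batch a alone, given below). In the FPKM, upper-quartile scaling turned the tissue differences of ripening from 2218 and 2367 to 2710 and 1989 in Frontenac and from 2241 and 1678 to 1817 and 2402 in Marquette, and left near-even numbers in Marquette skin (4353 and 4280), for tissue (6804 and 6552 in Frontenac, 6356 and 6236 in Marquette) and for the cultivar difference of tissue (2537 and 2663). Leaving out 1 library also turned the FPKM balance in Frontenac pulp and for cultivar in skin. The 16 changes named from the FPKM kept their direction and call in every alternative run, and those named from the counts lost a call 23 times, 10 of these for Vitvi14g02659. The alternatives for the former all refit the gene-rich FPKM, and the counts of some of these identifiers, given above, did not show the change. In simulated counts edgeR recovered 40.9% of 8-fold changes with ripening. Except where fewer libraries or genes enter by construction, the cause of each shift was not tested.

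With RLE size factors the counts gave 1478 genes in Marquette pulp, 77 and 43 for the cultivar differences of ripening in pulp and skin, and 315 for the tissue difference of ripening in Marquette. RLE moved the median log2 change of all genes by −0.60 in Marquette pulp, −0.12 in Frontenac pulp and 0.11 in Marquette skin, and by 0.19 and 0.16 for cultivar in pulp and skin. It moved those medians by −0.45 and 0.19 for the cultivar differences and 0.72 for the Marquette tissue difference, and upper-quartile scaling moved the FPKM skin cultivar difference by −0.12. The DESeq2 Wald test gave 1839 in Marquette pulp, 572 in Marquette skin, 207 and 74 for the cultivar differences of ripening, 69 and 651 for the tissue differences in Frontenac and Marquette, and 215 for the cultivar difference of tissue. Without the filter on low counts there were 149 in Frontenac pulp, 333 in Frontenac skin, 178 in Marquette skin, 2435 for tissue in Frontenac, 7 and 10 for the cultivar differences of ripening, 9 for the tissue difference in Frontenac and 53 for the cultivar difference of tissue. A linear slope over Brix gave 68 and 54 for the cultivar differences of ripening and 103 for the tissue difference in Marquette.

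With only the groups of a comparison in the fit, the counts gave 986 in Frontenac pulp, 1431 in Frontenac skin, 8 in Marquette pulp, 1284 in Marquette skin, 0 for the cultivar difference of ripening in pulp (edgeR, 268 at an unadjusted p under 0.05), and 159 and 10 for the tissue differences in Frontenac and Marquette. The FPKM gave 5379 in Frontenac pulp, 5558 in Marquette pulp, 5383 in Marquette skin, 1188 for the cultivar difference in pulp and 1973 for the tissue difference in Marquette.

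Limma on the FPKM of all 64 libraries, over the genes of the counts, gave 36 in Frontenac pulp, 77 in Frontenac skin, 29 in Marquette pulp, 39 in Marquette skin, 833 and 741 for tissue in Frontenac and Marquette, and 226 and 333 for cultivar in pulp and skin. It gave 0 and 3 for the cultivar differences of ripening (the 0 with 96 at an unadjusted p under 0.05), 5 and 3 for the tissue differences and 36 for the cultivar difference of tissue. With a pseudocount of 0.1 these were 25, 41, 5, 22, 748, 619, 217, 288, 0, 0, 1, 0 and 23 in the same order, each 0 by limma and beside 107, 126 and 94 genes at an unadjusted p under 0.05.

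Batch a of the rule alone gave 27 in Frontenac pulp, 120 in Frontenac skin, 36 in Marquette skin, 925 and 897 for tissue in Frontenac and Marquette, and 0 (edgeR, 164 at an unadjusted p under 0.05) and 4 for the tissue differences of ripening, for which batch b gave 54 and 20. For comparisons between the cultivars a batch alone was not run, since each batch holds different library sets in the 2 cultivars. In its place the gene-rich set gave 803 for cultivar in skin, 4 and 0 (edgeR, 196 at an unadjusted p under 0.05) for the cultivar differences of ripening and 8 for that of tissue, and the gene-poor set gave 96 and 101 for the differences of ripening. The library set as the batch term gave 1719 in Marquette pulp, 78 and 52 for the cultivar differences of ripening and 257 for the tissue difference in Marquette. Without the 2 libraries of highest total count there were 487 in Marquette pulp, 565 in Marquette skin, 69 for the cultivar difference in skin and 53 for the tissue difference in Frontenac, and in the FPKM 2584 for the cultivar difference in pulp. Both changes together gave 956 in Frontenac pulp, 1314 in Frontenac skin, 1134 in Marquette skin, 101 and 214 for the cultivar differences of ripening, 119 and 175 for the tissue differences and 276 for the cultivar difference of tissue.

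With skin and pulp of the same berries as a block, the FPKM gave 1897 genes for the cultivar difference of tissue against 5345 unpaired, and the counts gave 109 for the tissue difference of ripening in Marquette against 62. The block for the tissue differences of ripening was chosen after seeing the data. The other results with the berry sample or the replicate number as a block stayed within 1.5 times their values. The gene lists could be tested neither by camera nor by fry, so these alternatives were not run.

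Leaving out each library in turn, the counts ranged over 270 to 360 (Frontenac pulp), 397 to 482 (Frontenac skin), 426 to 1325 (Marquette pulp), 239 to 290 (Marquette skin), 1530 to 1577 (tissue in Frontenac), 1378 to 1554 (tissue in Marquette), 1225 to 1534 (cultivar in pulp), 1119 to 1262 (cultivar in skin), 7 to 72 (the cultivar difference of ripening in pulp), 15 to 27 (in skin), 14 to 31 (the tissue difference of ripening in Frontenac), 37 to 337 (in Marquette) and 104 to 165 (the cultivar difference of tissue). In the FPKM, where a level of ripening is then left with 1 library that is assumed to vary like the other groups, they ranged over 6282 to 8204 (Frontenac pulp), 6983 to 8232 (Frontenac skin), 7162 to 8121 (Marquette pulp), 6704 to 8939 (Marquette skin), 12581 to 12983 (tissue in Frontenac), 11738 to 12564 (tissue in Marquette), 9952 to 10519 (cultivar in pulp), 9681 to 10746 (cultivar in skin), 2560 to 3837 (the cultivar difference of ripening in pulp), 2692 to 4471 (in skin), 3406 to 4380 (the tissue difference of ripening in Frontenac), 2453 to 4582 (in Marquette) and 4769 to 6055 (the cultivar difference of tissue).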

Other observations

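All tests of single steps between Brix levels, and the counts of genes that moved in opposite directions, were chosen after seeing the data; the other splits of the libraries were planned, but the choice of those that keep the library sets equal on both sides was made later, as was that of those that keep skin and pulp together.

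The change with ripening was spread unevenly over the Brix levels in the FPKM of the gene-rich libraries (limma, 2 libraries per level). From 18 to 20 °Brix 7428 genes were called in Marquette skin and 6569 in Marquette pulp, against 1756 in Frontenac skin and 5370 in Frontenac pulp. From 22 to 24 °Brix there were 3002, 1622, 2506 and 264. Among genes that changed at least 2-fold from 18 to 24 °Brix, the step from 18 to 20 °Brix made up a median of 75.5% of the log2 change in Marquette skin, 60.3% in Marquette pulp, 50.7% in Frontenac pulp and 29.6% in Frontenac skin. In Frontenac skin the step from 20 to 22 °Brix made up 44.4%, and in Marquette skin 2.86%. A direct test found that the step from 18 to 20 °Brix differed between the cultivars for 4486 genes in pulp and 3094 in skin, that from 20 to 22 °Brix for 3191 and 3770, and that from 22 to 24 °Brix for 39 and 347. With 2 libraries per level these step counts move with single libraries, where the lone library left is assumed to vary like the other groups. Without the library that lowered it most, the first step gave 5201 in Marquette skin (without 18 °Brix replicate 4), 4039 in Marquette pulp (without 20 °Brix replicate 2), 819 in Frontenac skin (without 20 °Brix replicate 3) and 3422 in Frontenac pulp (without 18 °Brix replicate 2), and the last step 60 in Frontenac pulp (without 24 °Brix replicate 3), 717 in Marquette pulp (without 24 °Brix replicate 3), 1128 in Frontenac skin (without 22 °Brix replicate 2) and 1659 in Marquette skin (without 22 °Brix replicate 4). The step from 20 to 22 °Brix gave 4945 in Frontenac skin (2598 without 20 °Brix replicate 2), 3891 in Frontenac pulp (2093 without 22 °Brix replicate 3), 3152 in Marquette skin (1437 without 22 °Brix replicate 3) and 2859 in Marquette pulp, which ran from 365 without 22 °Brix replicate 3 to 4137 without 22 °Brix replicate 4. The tests of a step between the cultivars were not repeated without single libraries.

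A smaller set of genes moved in opposite directions, past the threshold on both sides and in the test of the difference (limma, FPKM). That test removed none of the genes called in opposite directions, and false calls on either side can enter these numbers. Independent calls would give more, at 2198 in pulp and 2172 in skin between cultivars. They would give 2164 in Frontenac and 2083 in Marquette between tissues, and 4036 for skin against pulp. With ripening in pulp, 110 genes rose in Frontenac and fell in Marquette and 206 did the reverse, and in skin 105 and 270. Between tissues, 135 genes rose in pulp and fell in skin with ripening in Frontenac and 255 did the reverse, against 135 and 220 in Marquette. For 164 genes skin was above pulp in Frontenac and below it in Marquette, and for 141 it was the other way round.

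Other splits of the same libraries were counted for the results with enough libraries per group. In the counts (edgeR), 1 of 35 splits, the real one, gave as many genes for ripening in Frontenac pulp (433, highest other 0), Frontenac skin (604, highest other 1) and Marquette skin (360, highest other 335), so over all 35 splits chance can be excluded at a share under 0.05. The split of 335 parted the gene-rich from the gene-poor libraries, and within those sets the result was 36 and 452. In Marquette pulp 4 of 35 splits gave at least the real 881 (highest other 1061), so chance cannot be excluded there. For the difference of ripening between cultivars, 2 of 35 splits gave as many genes in pulp (34, highest other 123), so chance cannot be excluded there. In skin only the real split did (26, 1 of 35, highest other 4), with the same limit as above. For the difference between tissues only the real split did so in Frontenac (32, 1 of 35, highest other 0), again with that limit. In Marquette 3 of 35 splits did (62, highest other 1002), so chance cannot be excluded. There a split with many times the real count points to a structure of the samples other than the groups. Many of these splits put unlike numbers of gene-rich libraries on the 2 sides. Only 18 of 35 keep 2 gene-rich and 2 gene-poor libraries on each side, and among these the smallest share that can be reached is 0.0556, so no share under 0.05 is possible there. Within them the highest other count was 0 in Frontenac pulp, 0 in Frontenac skin, 144 in Marquette pulp and 1 in Marquette skin. For the differences 11 and 10 splits (between cultivars in pulp and skin) and 8 and 11 (between tissues in Frontenac and Marquette) do so, with highest others of 2, 1, 0 and 41. The splits for the difference between tissues do not keep the skin and pulp of a berry sample together. With whole samples split in all 35 ways and the sample as a block (edgeR), the real split gave 36 in Frontenac (highest other 1) and 109 in Marquette (highest other 3), and among the 18 that keep the library sets equal the highest others were 0 and 1. For Marquette the outcome over all 35 splits thus differs between the unpaired and the paired count.

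For each of the tissue and cultivar results 1 of 35 drawn splits in the counts, the real one, gave as many genes, a share under 0.05 over these draws. The draws do not keep the gene-rich and gene-poor libraries equal on both sides, and those that do were not counted apart. Other splits also mix skin with pulp, or the cultivars, within a group, which widens the residual spread. The draws in the counts therefore do not exclude chance by themselves. The real values and the highest others were 1588 and 2 for tissue in Frontenac, 1434 and 227 for tissue in Marquette, 114 and 1 for the difference between them, 1357 and 1 for cultivar in pulp and 1213 and 36 for cultivar in skin. In the FPKM (limma) 1 of 100 drawn splits did so for each, with 13113 and 8468 for tissue in Frontenac, 12329 and 7201 for tissue in Marquette, 5345 and 3755 for the difference between them, 10634 and 5104 for cultivar in pulp and 10464 and 3955 for cultivar in skin. For tissue the real split parts skin from pulp in all 32 berry samples of the counts and in all 15 with both tissues in the gene-rich libraries, whereas the other splits part 12 to 26 and 5 to 15 of them. With the berry sample as a block the FPKM difference between the cultivars was 1897, below that 3755. Splits that keep the skin and pulp of a berry sample together were therefore counted with that block, exchanging the tissues within samples, or whole samples between cultivars for the difference. The real one was again the only 1 of 100 in the FPKM (11776, highest other 3333, for tissue in Frontenac, 10006 and 6394 in Marquette, 1897 and 30 for the difference, limma) and of 35 in the counts (1712 and 1180, 1466 and 0, 86 and 0, edgeR). The ripening results of the FPKM rest on 2 libraries per level and were given no such count.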
